A study of Gallus gallus with 9 samples.

How the data were processed

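Spleens of 4-week-old specific pathogen free White Leghorn chickens were sampled 24 h after an intramuscular injection. Total RNA was sequenced from 9 birds in 3 groups of 3, and each library was assigned to its group by its title. Control birds received PBS. The dual group received R-848, a small-molecule agonist of the receptor encoded by TLR7, with CpG-ODN, unmethylated CpG DNA that is sensed through TLR21 in chickens. The triple group received both of these with lipopolysaccharide (LPS), the ligand of the receptor encoded by TLR4.

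The deposited values are counts of read pairs per Ensembl gene, with 1 column per library and no normalisation. Per the file headers, featureCounts assigned pairs against Ensembl release 110 on the GRCg7b assembly. No option for strand, multi-mapping or overlapping features was set. A gene and its antisense partner are therefore not told apart, and near-identical gene copies can lose reads. The submitters' processing notes name FastQC 0.12.0, fastp 0.22.0, HISAT2 2.2.1 and featureCounts 2.0.3. All per-sample columns were used. Assigned pairs ranged from 10882716 in triple replicate 3 to 71378094 in control replicate 2.

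The 30108 genes of the count table carry Ensembl identifiers only. Names were taken by position from a RefSeq gene table of the same assembly. For 15381 genes the Ensembl and RefSeq spans were each other's best match and shared at least 50% of their union. For another 472 genes, the span of a protein-coding RefSeq gene lay at least 90% inside the Ensembl gene. At least 25% of the Ensembl gene's exon bases lay in that span. These 15853 named genes held 90.0% of all counts, and 13282 have a symbol that is not a placeholder. Another 526 genes with ambiguous matches stayed unnamed. The RefSeq table holds no strand, so a name can in principle belong to an overlapping gene on the other strand.

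Counts were analysed with edgeR 4.0.16 and limma 3.58.1 in R 4.3.3. The 14450 genes passing filterByExpr were scaled with TMM factors. The robust quasi-likelihood test (two-sided) was run in a single fit of all 9 libraries with 1 coefficient per group. The 4 comparisons were dual against control, triple against control, triple against dual, and the mean of both treatments against control. P-values were adjusted by Benjamini-Hochberg over all genes tested. A gene is called changed at an adjusted p below 0.05 with no fold minimum. The standard error (SE) of a log2 fold change is the value implied by the F statistic. CPM values are TMM-normalised unless stated, and are given as mean ± SD over the 3 libraries of a group. Intervals of shares are 95% Wilson intervals and cover counting error only.

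In all, 25 gene lists were fixed, covering pathways, cell types, neighbouring organs, and RNA quality and handling. Lists with at least 5 tested genes were tested with camera on log2 CPM (prior count 2, preset correlation 0.01, Benjamini-Hochberg over the lists). Camera with an estimated correlation and fry were run beside it. The pancreas list had too few tested genes for this.

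Genes are named by a rule applied to each comparison between single groups. It takes up to 6 called genes with the largest rise and up to 6 with the largest fall. These must carry a symbol, average at least 1 CPM and not overlap between the groups. It adds up to 3 genes per list with the smallest p. In every comparison it adds TLR4, TLR7, TLR21, IFNG, IL1B, IL6, IL10, NOS2 and MX1. Genes outside the rule are marked as chosen after their values were seen. The main tests, lists, naming rule and alternatives were set before the data were examined, with these exceptions. For cell-cycle genes, the cut-offs of the tests of sex, scaling and control replicate 2 were set from the list's observed median. The tests of sex and of dual replicate 1 on B cell and MHC class II genes were set for a difference already seen. The sex term, the medians within a sex, the test for a treatment response that differs between the sexes, the thinned library, the divided controls, the heterophil test and the medians of B cells and MHC class II presentation taken singly were chosen after seeing the data. The group means of AMY2A and GCG had been seen before the pancreas tests were set.

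The test was checked on counts simulated from these libraries for 14046 genes. For dual against control it recovered 17.3% of genes changed by a log2 fold of 1 and 76.1% of those changed by 2, with 10 false calls among 97. For triple against control the shares were 13.3% and 72.8%, with 5 false calls among 85. For both treatments they were 37.8% and 85.9%, with 9 false calls among 125. Between triple and dual, where nothing was simulated to differ, 1 gene was called.

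The alternatives tried were RLE factors, upper-quartile factors, library size only, no low-count filter, and a filter of at least 5 CPM in 3 libraries. Further ones were DESeq2 1.42.0, limma-voom, the replicate number as a block, a fit of only the groups compared, and a log2 fold minimum of 1. The haemoglobin genes named here (HBA1, HBAD and HBZ) and mitochondrial genes were removed in another, and each library was left out in turn. Chosen after seeing the data were a term for the sex of the bird, and a random thinning of control replicate 2 to the mean depth of the other 2 control libraries. Sex was read from the share of counts on chromosome W, with 0.05% separating the sexes. A fit with treatment (both mixes together), sex and their product tested for a response that differs between the sexes. The highest share in a male was 0.019% (interval 0.0188 to 0.0201) and the lowest in a female was 0.09% (interval 0.0886 to 0.0911). The correlation of both responses expected without any effect came from 100 simulations of unchanged groups sharing the control libraries. Each gene was drawn independently in them. After seeing the data, the control libraries were also divided 1 against 2 between the comparisons, in all 6 ways, in a fit with 4 groups. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.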

Results

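Spleen RNA was profiled in 9 White Leghorn chickens 24 h after injection of PBS, of a dual mix of TLR agonists (R-848 and CpG-ODN) or of a triple mix (LPS, R-848 and CpG-ODN), with 3 birds per group. Control replicates 1 to 3 had 18911567, 71378094 and 19150045 assigned read pairs. The dual group had 18389694, 12473943 and 18221688, and the triple group 20694027, 14203290 and 10882716. Across genes, which are not independent replicates, log2 CPM correlated at 0.939 to 0.975 within groups and at 0.925 to 0.975 between groups. Counts on chromosome W marked 4 birds as female: control replicate 3, dual replicates 1 and 2, and triple replicate 1. In triple replicate 1, pancreas genes took 0.407% of counts (95% Wilson interval 0.405 to 0.41), against at most 0.00211% (0.00201 to 0.00222, control replicate 2) in the other libraries.

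**Figure D1:**
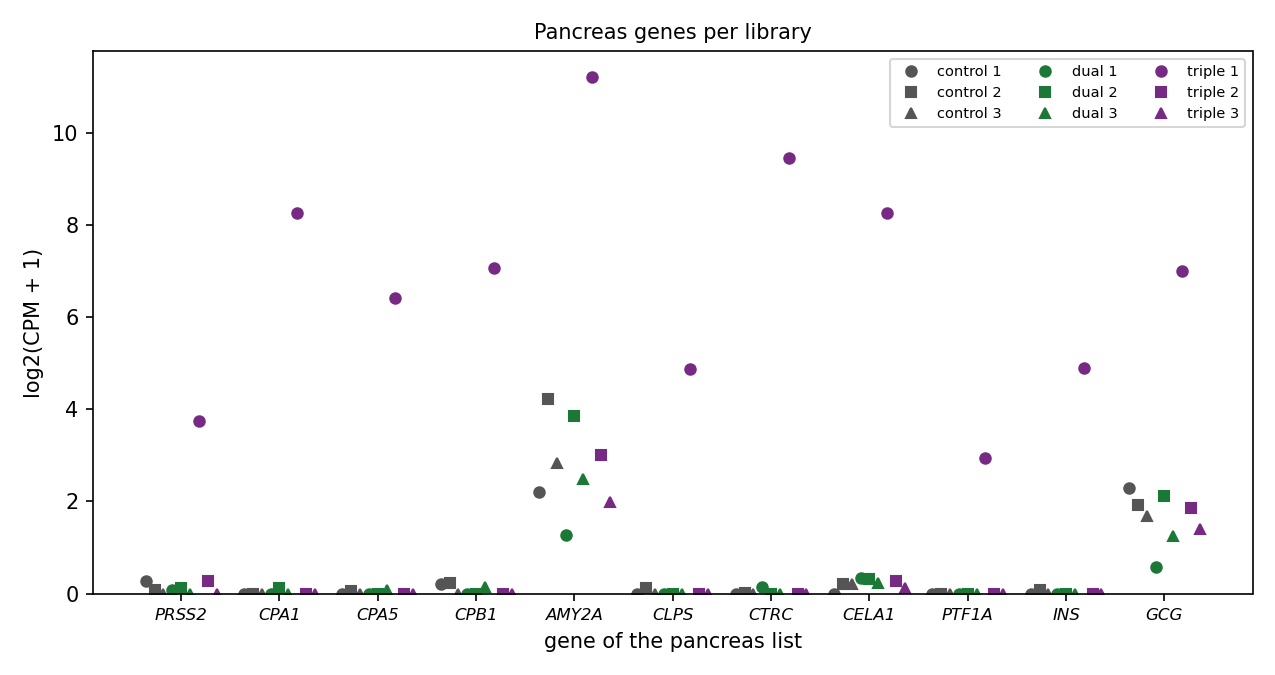
Expression of 11 genes of the pancreas list (horizontal axis) in each of the 9 libraries, as log2 of CPM plus 1 (vertical axis, CPM by library size). AMY2A stands at 2350 CPM in triple replicate 1 and at most at 17.7 CPM in the other libraries.

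The first comparison asked what the dual mix changed in the spleen. AVD, which encodes the biotin-binding protein avidin, rose most, from 4.28 ± 1.11 CPM in controls to 310 ± 144 CPM (SD, n = 3; log2 fold change 6.19, SE 0.42, edgeR adjusted p = 5.23e-05). The chemokine gene CXCL13L2 rose from 59.9 ± 22.4 to 579 ± 82.6 CPM (log2 3.27, SE 0.37, edgeR adjusted p = 0.00723). EXFABP, a siderophore-binding lipocalin, rose from 224 ± 67.2 to 1360 ± 451 CPM (log2 2.6, SE 0.33, edgeR adjusted p = 0.0187). The interferon-induced gene OASL (log2 1.96, SE 0.34), the decoy receptor gene IL13RA2 (1.92, SE 0.3), UBE2U (1.83, SE 0.33) and the complement protease gene C1S (1.24, SE 0.21) also rose. The collagenase gene MMP13 (log2 -2.7, SE 0.42), the chemokine receptor gene CCR8L (-2.21, SE 0.42), KCNMB2 (-1.66, SE 0.31), the T cell costimulatory gene ICOS (-1.35, SE 0.23) and CLEC3B (-1.33, SE 0.24) fell.

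On GRCg7b, AVD (ENSGALG00010011634) lies on chromosome Z at 9717630 to 9719023, CXCL13L2 (ENSGALG00010008206) on chromosome 4 at 34562640 to 34563675, and EXFABP (ENSGALG00010028912) on chromosome 17 at 1177676 to 1180692. AVD, CXCL13L2 and EXFABP have related copies in the genome, and reads that match several copies may have been lost. In all, 59 of 14450 genes changed in the dual group, 53 higher and 6 lower. An unadjusted p below 0.05 was found for 2110 genes, where chance gives 722.

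Cell-cycle genes rose together in the dual group. All 32 tested genes had positive fold changes (median 0.96), of which 8 rose over all genes and 31 adjusted over the list alone. The replication gene MCM3 rose from 41.7 ± 3.3 to 123 ± 38.6 CPM (log2 1.56, SE 0.23), the mitotic kinase gene PLK1 by log2 1.56 (SE 0.24) and the topoisomerase gene TOP2A by log2 1.45 (SE 0.23). The list passed camera (adjusted p = 3.12e-26) and was the only list in this comparison to hold as well with an estimated correlation (adjusted p = 0.000387 with an estimated correlation). Its median was 0.95 in the females (2 treated, 1 control) and 1.05 in the males (1 treated, 2 controls).

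Interferon-stimulated genes were higher as a set, with 29 of 30 positive (median 0.69, camera adjusted p = 4.16e-10; adjusted p = 0.25 with an estimated correlation). OASL rose over all genes, and 9 genes rose adjusted over the list alone. TRIM25 (log2 0.85, edgeR adjusted p = 0.0728), DHX58 (log2 1.24, edgeR adjusted p = 0.0786) and MX1 (12.8 ± 9.62 and 35.1 ± 12.6 CPM, edgeR adjusted p = 0.275) did not pass. Cholesterol and lipid synthesis genes had 18 of 20 positive (median 0.62, camera adjusted p = 5.22e-07; adjusted p = 0.25 with an estimated correlation). None of them passed over all genes and 10 rose adjusted over the list alone. FDPS stood at log2 1.52 (edgeR adjusted p = 0.0955) and LSS at log2 1.25 (edgeR adjusted p = 0.09).

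MHC class I presentation genes had 13 of 14 positive (median 0.62, camera adjusted p = 3.29e-05; adjusted p = 0.25 with an estimated correlation). No single gene passed, over all genes or adjusted over the list alone. TAP1, a peptide transporter subunit, stood at log2 0.89 (edgeR adjusted p = 0.194) and the class I gene BF2 at log2 0.92 (edgeR adjusted p = 0.253). Plasma cell markers had 7 of 8 positive (median 0.85, camera adjusted p = 0.0089; adjusted p = 0.532 with an estimated correlation). None passed over all genes and 4 rose adjusted over the list alone. TXNDC5 stood at log2 1.47 (edgeR adjusted p = 0.133). The call of plasma cells was lost without dual replicate 1 (0.0634) or dual replicate 3 (0.075).

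T cell markers were lower as a set in the dual group, with all 21 negative (median -0.35, camera adjusted p = 0.000481; adjusted p = 0.532 with an estimated correlation). ICOS fell over all genes and adjusted over the list alone. All 15 endothelial markers were negative (median -0.51, camera adjusted p = 5.64e-05; adjusted p = 0.25 with an estimated correlation). None passed over all genes and 2 fell adjusted over the list alone. The angiopoietin receptor gene TEK stood at log2 -1.15 (edgeR adjusted p = 0.113) and EMCN at log2 -0.87 (edgeR adjusted p = 0.116). Thrombocyte markers were negative for 9 of 11 (median -0.59, camera adjusted p = 0.035; adjusted p = 0.605 with an estimated correlation). None passed over all genes and 1 fell adjusted over the list alone. The call of thrombocytes was lost without control replicate 3 (0.507), dual replicate 1 (0.0577) or dual replicate 3 (0.379).

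The count of 59 was 2, 2 and 1 without control replicates 1, 2 and 3. It was 3, 1005 and 5 without dual replicates 1, 2 and 3, and 5, 5 and 4 without triple replicates 1, 2 and 3, which share the estimate of the spread. With a term for sex it was 3 (AVD, CXCL13L2 and EXFABP). The 59 genes then had a median fold size of log2 1.51 (before, 1.53) with a median SE of 0.27 (before, 0.26) and 5 residual degrees of freedom (before, 6), no fold moved by more than its SE, and the adjusted p was at most 0.0884. AVD passed whichever library was left out (edgeR adjusted p at most 0.0017). CXCL13L2 lost its call without control replicate 3 (0.0696), and EXFABP without control replicates 1 (0.0905), 2 (0.0985) or 3 (0.0987). The other named genes that rose or fell lost theirs without 7 or 8 of the 9 libraries, always including the control libraries, with an adjusted p of up to 0.205. Without dual replicate 2, TRIM25, DHX58, FDPS, LSS, TAP1, TXNDC5, TEK and EMCN passed, with an edgeR adjusted p between 0.00592 (FDPS) and 0.0405 (EMCN).

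The second comparison asked the same of the triple mix. AVD rose to 671 ± 65 CPM (SD, n = 3; log2 7.3, SE 0.44, edgeR adjusted p = 1.32e-05), EXFABP to 2950 ± 232 CPM (log2 3.72, SE 0.35, edgeR adjusted p = 0.000983) and CXCL13L2 to 585 ± 215 CPM (log2 3.29, SE 0.37, edgeR adjusted p = 0.00277). ATP6V0D2, a subunit of the vacuolar proton pump (log2 3.64, SE 0.53), the neuropeptide gene NPW (3.51, SE 0.61) and IL4I1, a secreted amino acid oxidase (3.26, SE 0.54), rose from low levels in controls. HMOX1, which degrades haem, rose from 416 ± 93.1 to 1200 ± 118 CPM (log2 1.53, SE 0.26), and C1S rose by log2 1.4 (SE 0.21). In all, 36 genes rose and none fell by edgeR, with 1558 genes at an unadjusted p below 0.05, while DESeq2 called 309 higher and 78 lower.

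**Figure D2:**
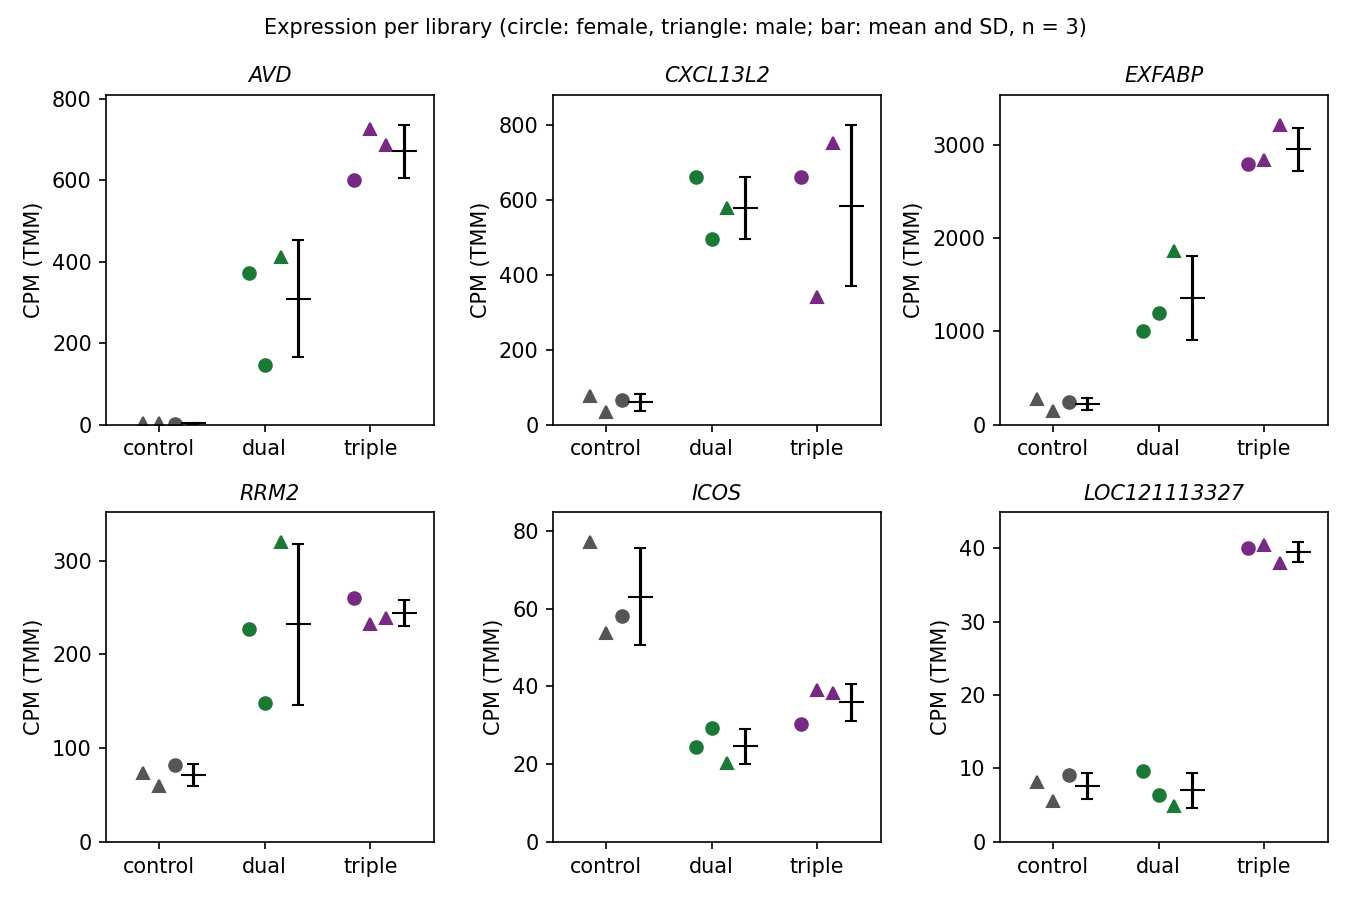
TMM-normalised CPM (vertical axes, linear from 0) of 6 genes in each library, by group; circles are females, triangles males, and bars give mean and SD over 3 libraries. AVD lies between 3.38 and 5.51 CPM in controls, between 146 and 412 in the dual group and between 600 and 726 in the triple group.

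Cell-cycle genes rose together here as well, with 32 of 32 positive and a median of 0.95 (camera adjusted p = 5.43e-29, adjusted p = 0.000288 with an estimated correlation). RRM2, a subunit of ribonucleotide reductase, rose over all genes, from 71.6 ± 11.5 to 244 ± 14 CPM (log2 1.77, SE 0.27). Adjusted over the list alone 31 rose. PLK1 stood at log2 1.28 and the cyclin gene CCNE2 at log2 1.12, each with an edgeR adjusted p of 0.0593. The median was 0.95 in the females (1 treated, 1 control) and 0.97 in the males (2 treated, 2 controls). No other list held with an estimated correlation.

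Interferon-stimulated genes were higher as a set in the triple group, with 29 of 30 positive (median 0.59, camera adjusted p = 2.29e-12; adjusted p = 0.302 with an estimated correlation). None passed over all genes and 13 rose adjusted over the list alone. OASL (log2 1.83, edgeR adjusted p = 0.0529), CMPK2 (log2 2, edgeR adjusted p = 0.0597), IFI6 (log2 1.62, edgeR adjusted p = 0.0618) and MX1 (50.7 ± 19.6 CPM, log2 1.99, edgeR adjusted p = 0.183) stood outside the threshold. Of 21 alternatives, OASL passed in 12, CMPK2 in 8, IFI6 in 6 and MX1 in 1. The set's median was 1.05 in the females and 0.45 in the males.

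Further sets were higher in the triple group by camera. MHC class I genes had 12 of 14 positive (median 0.4, camera adjusted p = 0.00107; adjusted p = 0.302 with an estimated correlation), and none passed over all genes or adjusted over the list alone. The same held for cholesterol and lipid synthesis genes, with 17 of 20 positive (median 0.55, camera adjusted p = 1.51e-05; adjusted p = 0.302 with an estimated correlation). Plasma cell markers had 7 of 8 positive (median 0.76, camera adjusted p = 0.000298; adjusted p = 0.302 with an estimated correlation), 0 over all genes and 3 adjusted over the list alone. Complement genes had 10 of 17 positive (median 0.44, camera adjusted p = 0.0201; adjusted p = 0.302 with an estimated correlation). C1S rose over all genes and 4 rose adjusted over the list alone. Apoptosis genes had 16 of 20 positive (median 0.13, camera adjusted p = 0.0366; adjusted p = 0.365 with an estimated correlation), and none passed either way. The call of apoptosis was lost without control replicate 2 (0.144), control replicate 3 (0.0962), triple replicate 1 (0.068) or triple replicate 2 (0.0782).

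Marker sets of several cell types were lower in the triple group by camera at the preset correlation. None of them passed with an estimated correlation or by fry. All 21 T cell markers were negative (median -0.53, camera adjusted p = 1.29e-07; adjusted p = 0.302 with an estimated correlation), with 0 past the test over all genes or adjusted over the list alone. MHC class II presentation genes were negative for 8 of 11 (median -0.66, camera adjusted p = 0.0201; adjusted p = 0.302 with an estimated correlation), with 0 over all genes and 2 lower adjusted over the list alone. The invariant chain gene CD74 stood at 11400 ± 1450 CPM in controls and 5500 ± 977 CPM in the triple group (log2 -1.06, edgeR adjusted p = 0.224). The call of MHC class II presentation was lost without control replicate 3 (0.0962). Cytotoxic lymphocyte markers were negative for 7 of 8 (median -0.28, camera adjusted p = 0.0216; adjusted p = 0.365 with an estimated correlation), with 0 over all genes and 3 lower adjusted over the list alone. Their median was -1.05 in the females and 0.06 in the males. The call of cytotoxic lymphocytes was lost without control replicate 3 (0.344) or triple replicate 1 (0.124).

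Erythroid markers were negative for 11 of 13 (median -0.48, camera adjusted p = 0.0154; adjusted p = 0.365 with an estimated correlation), and all 15 endothelial markers were negative (median -0.23, camera adjusted p = 0.0314; adjusted p = 0.324 with an estimated correlation). No gene of either list passed over all genes or adjusted over the list alone. The call of erythroid cells was lost without control replicate 1 (0.0585), control replicate 3 (0.0962) or triple replicate 2 (0.126). That of endothelial cells was lost without control replicate 1 (0.0918), control replicate 3 (0.0727), triple replicate 2 (0.159) or triple replicate 3 (0.0644). Among dendritic cell markers, a list that did not pass, the receptor gene FLT3 stood at 21.9 ± 3.96 CPM in controls and 3.52 ± 1.6 CPM in the triple group (log2 -2.64, edgeR adjusted p = 0.0618).

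The count of 36 was 5, 5 and 9 without control replicates 1, 2 and 3, and 8, 13 and 12 without triple replicates 1, 2 and 3. It was 144, 174 and 85 without dual replicates 1, 2 and 3, which share the estimate of the spread. AVD, EXFABP and CXCL13L2 passed whichever library was left out (edgeR adjusted p at most 0.0226). ATP6V0D2, NPW, IL4I1, C1S, HMOX1 and RRM2 lost their calls without 5 or 6 of the libraries, always including the control libraries, with an adjusted p of up to 0.185. OASL, CMPK2, IFI6, PLK1 and CCNE2 passed without any 1 of dual replicates 1, 2 and 3 (lowest edgeR adjusted p 0.0171, PLK1), and FLT3 without dual replicate 1 or 2 (lowest 0.00723).

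The genes of the receptors for the 3 agonists did not pass the test in either treated group. TLR4 stood at 50.8 ± 7.12 CPM in controls, 61.1 ± 6.94 in the dual and 71.4 ± 8.91 in the triple group (SD, n = 3). TLR7 stood at 47.6 ± 2.47, 51.4 ± 12.4 and 37.5 ± 5.83 CPM, and TLR21 at 39.3 ± 3.33, 56.3 ± 25.7 and 34.6 ± 4.08 CPM. The smallest edgeR adjusted p among these was 0.38. The inflammatory cytokine gene IL1B stood at 2.34 ± 0.978 CPM in controls, 4.29 ± 1.88 in the dual group (edgeR adjusted p = 0.362) and 9.47 ± 1.15 in the triple group (log2 2.01, SE 0.42, edgeR adjusted p = 0.0659). In the triple group it passed in 6 of 21 alternatives. Among these were the fits without dual replicate 1 or 2 (lowest edgeR adjusted p 0.0306).

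IL6 stood at 0.725 ± 0.262, 1.86 ± 1.06 and 2.38 ± 0.406 CPM in the control, dual and triple groups, IFNG at 0.808 ± 0.196, 1.15 ± 0.891 and 1.9 ± 0.829 CPM, and NOS2 at 22.4 ± 2.27, 16.1 ± 7.45 and 17.9 ± 1.04 CPM. Their edgeR adjusted p against control was 0.201 or more. IL10, with 3 to 26 counts per library, was too low to test. Lists that did not pass camera against control in either group were cytokines, chemokines and chemokine receptors, Toll-like receptors and signalling, immune inhibitory regulators, B cells, macrophages, dendritic cells, heterophils, stromal cells, liver, and RNA quality and handling stress. Their camera adjusted p was 0.0681 or more. In the dual group, B cells passed without control replicate 2 (0.0141) or dual replicate 3 (0.0264), and stromal cells without control replicate 1 (0.0159). In the triple group, dendritic cells passed without dual replicate 1 (0.0407) or triple replicate 2 (0.0394), and macrophages without control replicate 1 (0.026) or triple replicate 1 (0.0392). For heterophils in the triple group the median was -0.82 while the test pointed upwards (camera adjusted p = 0.854).

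**Figure D3:**
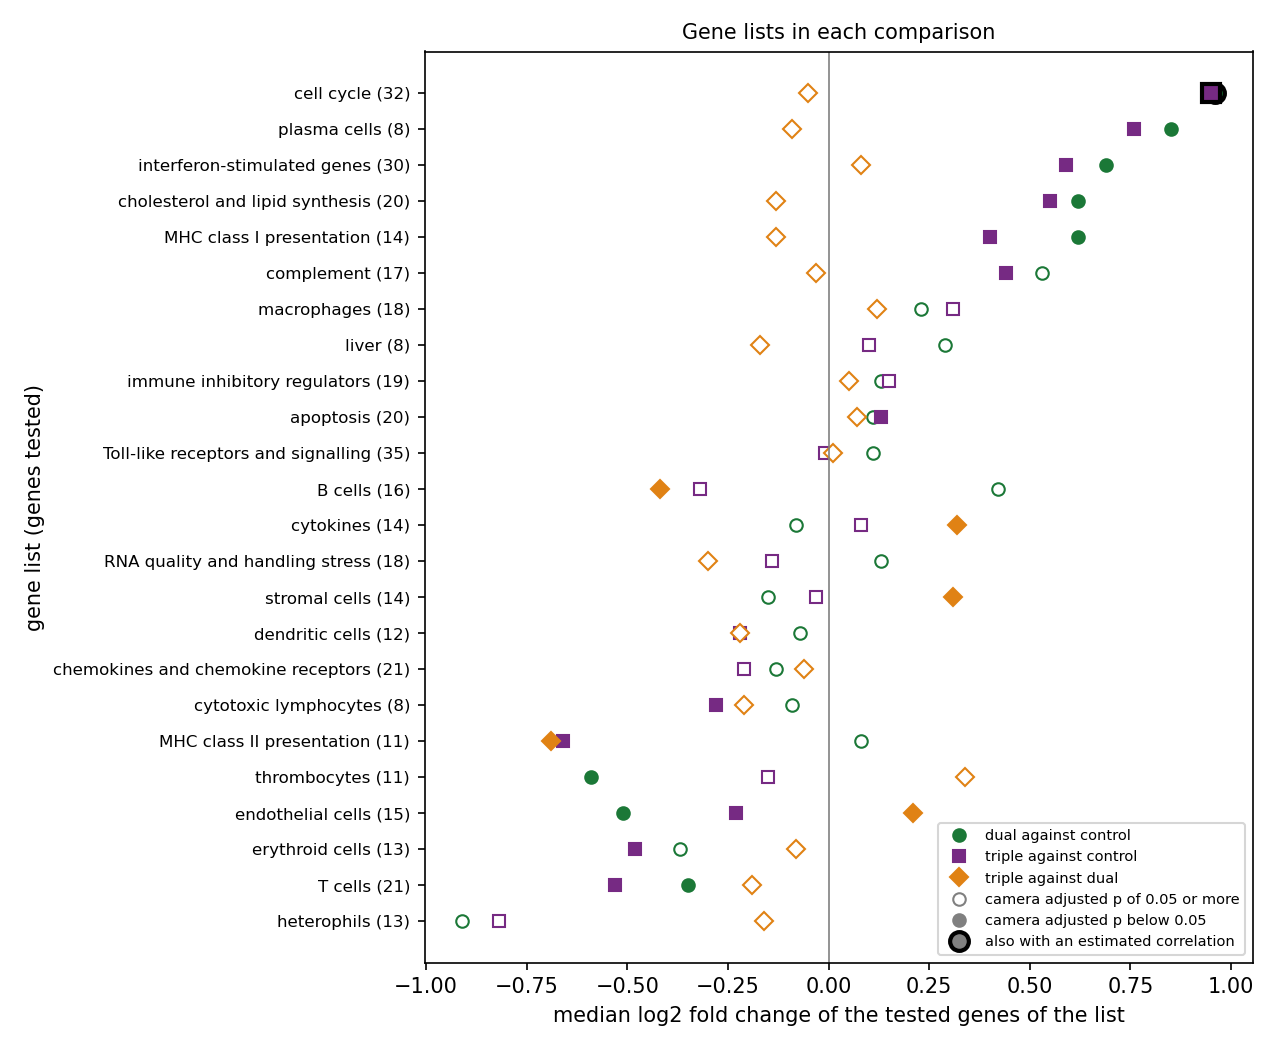
Median log2 fold change (horizontal axis) of the tested genes of each list (vertical axis, genes tested in brackets) in 3 comparisons; filled symbols passed camera at the preset correlation, and black edges mark those that also passed with an estimated correlation. The cell cycle list lies at 0.96 and 0.95 against control and at -0.05 between triple and dual, where it is 0 with library size only.

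Triple against dual tested the addition of LPS directly. LOC121113327 (ENSGALG00010007160), an uncharacterised gene named after its values were seen, was the only gene to change by edgeR. It lies on chromosome 1 at 163071 to 167700 and stood at 7.61 ± 1.81 CPM in controls, 7.01 ± 2.43 in the dual and 39.5 ± 1.35 in the triple group (SD, n = 3; log2 2.49 against dual, SE 0.3, edgeR adjusted p = 0.0257). An unadjusted p below 0.05 was found for 710 genes, where chance gives 722, and DESeq2 called 14 genes. The chemokine gene IL8L1 stood at 1.26 ± 0.449 CPM in the dual and 6.07 ± 0.939 CPM in the triple group (log2 2.25, SE 0.37, edgeR adjusted p = 0.377). DESeq2 called IL8L1 (adjusted p = 6e-05), and over all alternatives the adjusted p ran up to 0.958. AVD differed by log2 1.11 (SE 0.34) and EXFABP by log2 1.12 (SE 0.32), each with an edgeR adjusted p of 0.886; both were chosen after their values were seen.

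B cell markers were lower in the triple than in the dual group as a set, with 15 of 16 negative (median -0.42, camera adjusted p = 0.000244; adjusted p = 0.301 with an estimated correlation). None passed over all genes and 1 was lower adjusted over the list alone. CD79B, part of the B cell receptor, stood at 577 ± 251 CPM in the dual and 318 ± 20.1 CPM in the triple group (log2 -0.86), and the survival receptor gene TNFRSF13C at 109 ± 80 and 36 ± 4.14 CPM (log2 -1.59). Neither passed by edgeR (adjusted p = 0.886 each), and DESeq2 called TNFRSF13C (adjusted p = 0.0454, up to 1 over all alternatives). Dual replicate 1 was highest, at 865 CPM for CD79B and 201 CPM for TNFRSF13C. Without it the log2 differences were -0.44 and -0.8. MHC class II presentation genes were negative for 9 of 11 (median -0.69, camera adjusted p = 0.00182; adjusted p = 0.301 with an estimated correlation), with 0 over all genes and 3 lower adjusted over the list alone. DMA stood at 391 ± 121 and 222 ± 36.8 CPM (log2 -0.82).

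Cytokine genes were higher in the triple than in the dual group for 11 of 14 (median 0.32, camera adjusted p = 0.0442; adjusted p = 0.301 with an estimated correlation). Stromal markers were higher for 11 of 14 (median 0.31, camera adjusted p = 0.0278; adjusted p = 0.708 with an estimated correlation), and endothelial markers for 10 of 15 (median 0.21, camera adjusted p = 0.0203; adjusted p = 0.465 with an estimated correlation). No gene of these lists passed over all genes or adjusted over the list alone. The call of cytokines was lost without dual replicate 2 (0.07), dual replicate 3 (0.244), triple replicate 1 (0.117) or triple replicate 2 (0.0715). That of stromal cells was lost without dual replicate 3 (0.422) or triple replicate 1 (0.257), and that of endothelial cells without dual replicate 1 (0.08), dual replicate 3 (0.164) or triple replicate 1 (0.134).

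The call of LOC121113327 was lost without control replicate 1 (edgeR adjusted p = 0.0722), dual replicate 2 (0.222), dual replicate 3 (0.0789) or triple replicates 1 (0.175), 2 (0.199) and 3 (0.186). The number of genes called was 0 without control replicate 1, dual replicate 2 or any of the triple replicates, and 2 without dual replicate 1.

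The mean of both treatments against control covered 6 treated birds, and the genes named for it were chosen after their values were seen. AVD (log2 6.74, SE 0.42, edgeR adjusted p = 1.89e-05), CXCL13L2 (3.28, SE 0.35, edgeR adjusted p = 0.00261) and EXFABP (3.16, SE 0.32, edgeR adjusted p = 0.00243) rose. Of the 32 cell-cycle genes, 17 rose over all genes and 31 adjusted over the list alone (median 0.94, camera adjusted p = 2.91e-30; adjusted p = 0.000254 with an estimated correlation). Among them were RRM2 (log2 1.73, SE 0.25), PLK1 (1.42, SE 0.22), MCM5 (1.41, SE 0.25) and CDC20 (1.34, SE 0.25). OASL (log2 1.9) and CMPK2 (1.74) rose among interferon-stimulated genes, C1S (1.32) among complement genes and HMOX1 (1.29) among macrophage markers. The macrophage list did not pass (median 0.25, camera adjusted p = 0.262). Adjusted over that list alone, 3 rose and 2 fell. XCR1 (log2 -1.69) and FLT3 (-2.04), both markers of dendritic cells, and ICOS (-1.08) fell. The dendritic cell list did not pass, with 4 of 12 positive (median -0.24, camera adjusted p = 0.145). Adjusted over that list alone, 1 rose and 2 fell.

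In all, 173 genes changed with both treatments, 142 higher and 31 lower, and 2106 genes had an unadjusted p below 0.05. The cell cycle list alone held with an estimated correlation, and its median was 0.98 in the females and 1 in the males. Interferon-stimulated genes were higher as a set (17 adjusted over the list alone, camera adjusted p = 6.33e-13; adjusted p = 0.266 with an estimated correlation), as were MHC class I genes (0, camera adjusted p = 3.95e-05; adjusted p = 0.266 with an estimated correlation). So were cholesterol and lipid synthesis genes (11, camera adjusted p = 3.58e-07; adjusted p = 0.266 with an estimated correlation), plasma cells (5, camera adjusted p = 0.000646; adjusted p = 0.321 with an estimated correlation) and complement (5, camera adjusted p = 0.0309; adjusted p = 0.286 with an estimated correlation). T cells were lower (1 adjusted over the list alone, camera adjusted p = 1.83e-06; adjusted p = 0.286 with an estimated correlation). So were endothelial cells (1, camera adjusted p = 0.000547; adjusted p = 0.266 with an estimated correlation) and erythroid cells (0, camera adjusted p = 0.0375; adjusted p = 0.591 with an estimated correlation). The call of complement was lost without dual replicate 1 (0.0523) or dual replicate 2 (0.198). That of erythroid cells was lost without control replicate 1 (0.111), control replicate 3 (0.281), dual replicate 1 (0.0891), dual replicate 2 (0.197) or triple replicate 2 (0.103), and with the sex term (0.0504).

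The count of 173 was 3, 4 and 9 without control replicates 1, 2 and 3. It was 197, 784 and 120 without dual replicates 1, 2 and 3, and 6, 30 and 27 without triple replicates 1, 2 and 3. AVD, CXCL13L2 and EXFABP passed whichever library was left out (edgeR adjusted p at most 0.0243). The other genes named for this comparison lost their calls without 4 to 8 of the libraries, always including the control libraries, with an adjusted p of up to 0.167.

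Both responses were set side by side for the genes they share. Called in both were 21 genes, all higher. Across genes, which are not independent replicates, the 2 sets of fold changes correlated at 0.65 (Spearman 0.639), against 0.485 (Spearman 0.455) in simulated unchanged groups with the same controls. They had the same sign for 73.37% of genes, against 66.296%, and their covariance was 0.228, against 0.14 ± 0.014. The correlation was 0.45 without triple replicate 1 and 0.48 without dual replicate 3, both under 0.485, and 0.52 without triple replicate 3, under the highest simulated value of 0.579. The simulations had all 9 libraries and were not repeated for fewer. They drew each gene independently, so variation that genes share between birds is left out. The simulated spread may therefore be too narrow. In an analysis chosen after seeing the data, the control birds were divided 1 against 2, so that the comparisons shared none. The correlation was then between 0.08 and 0.33 (mean 0.23) over the 6 divisions. The simulated 0.485 comes from shared controls and does not apply to these values. No value without any effect was simulated for the divisions. In each of them 1 comparison rests on a single control bird. The 21 shared genes became 2, 2 and 1 without control replicates 1, 2 and 3, and 4 without any 1 of the triple replicates. They became 3, 136 and 3 without dual replicates 1, 2 and 3.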

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

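The sex term, the test for a response that differs between the sexes and the medians of B cells and MHC class II presentation taken singly were chosen after the data were seen. The cut-offs of the cell-cycle tests were set from the list's observed median. The tests on B cell and MHC class II genes were set for a difference already seen. The group means of AMY2A and GCG had been seen before the pancreas tests were set.

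LOC121113327 stands out because a direct test found the responses to the 2 mixes to differ, with a log2 difference of 2.49. Of the 10 splits of those 6 libraries, 2 called as many genes as the real 1, and the highest other called 1. Lists stand out for the same reason, by camera adjusted p: cytokines (0.0442), MHC class II presentation (0.00182), B cells (0.000244), stromal cells (0.0278) and endothelial cells (0.0203). Of the 10 splits, 3 put at least the real 5 lists past the test, and the highest other put 9 past it. For 10 splits no share under 0.05 can be had.

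B cell and MHC class II genes were lower in the triple than in the dual group, with a median of -0.45 over both lists. An unequal sex ratio would shrink this with a sex term, and the median stayed at -0.45. Dependence on dual replicate 1, the library farthest out on the first principal component, would shrink it without that library, and it was -0.41 (B cells from -0.42 to -0.36, MHC class II presentation from -0.69 to -0.54). The values argue against either as the whole cause, but that library contributes, since 6 of the 15 negative B cell genes shrank by more than 50% without it. An effect of LPS may remain as an untested hypothesis, and chance stays open.

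Pancreas genes stand out as a signal in genes mostly left untested: 11 genes had in triple replicate 1 at least 10 times the CPM of every other library, and 2 of these 11 passed the low-count filter. Besides AMY2A at 2350 CPM, CTRC stood at 698, CELA1 at 305, CPA1 at 304, and the endocrine genes GCG and INS at 127 and 28.5 CPM. A response to the triple mix would place the other triple libraries above all control and dual libraries, which held for 0% of these genes. Tissue of the neighbouring pancreas in that sample is a candidate explanation, for which the value of 11 is what it would give. AMY2A and GCG had counts in all 9 libraries, and the source of those outside triple replicate 1 was not tested.

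Cell-cycle genes were higher in both treated groups, with a median of 0.94. The median was 0.94 with a sex term, at least 0.85 over the other scalings, and 0.96 without the deep control replicate 2, which argues against sex, scaling and that library. Of the 84 splits of the 9 libraries into 3 and 6, 1 (the real one) gave a median as large, and the highest other was 0.52. No smaller share can be had from 84 splits, and the list had the lowest camera p of those tested. Chance is thus made less likely but is not excluded. Proliferation after TLR agonists may be raised as a hypothesis from these same data, but neither it nor a shift towards cell types that divide more was tested.

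ENSGALG00010002949 on chromosome 1 was the only gene past the test for a treatment response that differs between the sexes (log2 -12.55, males minus females, edgeR adjusted p = 0.0325), which rests on 1 library: control replicate 3, the only female control, had 4 counts against 8264 to 165958 in the other libraries, and 600 genes had an unadjusted p below 0.05, where chance gives 722.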

How the results depend on the processing

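The sex term, the thinning of control replicate 2 and the divided controls were chosen after seeing the data. Counts of called genes moved widely. Some fits had fewer libraries, and the cause was not tested. For dual against control, the 59 calls became 33 with upper-quartile factors, 15 with library size only (which moves the median of all genes from 0.01 to -0.12), 173 without a low-count filter, 487 with DESeq2, 2 with only the groups compared and 3 with the sex term. They ranged from 1 to 1005 over libraries left out. For triple against control, the 36 became 124 without the filter, 387 with DESeq2, 68 with limma-voom and 528 with only the groups compared, and ranged from 5 to 174. For triple against dual, the 1 call became 2 without the filter, 14 with DESeq2 and 0 with only the groups compared, and ranged from 0 to 2. For both treatments, the 173 became 100 with library size only and 613 with DESeq2, and ranged from 3 to 784. DESeq2 called 58 of the 59, all 36 and all 173. Replicate numbers did not pair the libraries (correlations of same-numbered deviations -0.26 to 0.2). With them as a block the calls were 15, 37, 0 and 135, with 11 shared by both responses. The 21 shared calls became 33 with the 5 CPM filter and 3 with the sex term, and ranged from 1 to 136. The correlation of both responses ranged from 0.45 to 0.8. With the controls divided, it was 0.24, 0.25 and 0.18 (dual against control replicate 1, 2 or 3 alone) and 0.33, 0.31 and 0.08 (triple against each alone). Lists past camera (8, 12, 5 and 9) became 1, 1, 0 and 1 with an estimated correlation and 5, 1, 0 and 5 with fry. For dual and for both treatments, fry passed cell cycle, interferon-stimulated genes, MHC class I presentation, cholesterol and lipid synthesis, and endothelial cells. Beyond cell cycle, the fry adjusted p was 0.0445 each for dual, and 0.0304 to 0.0469 for both treatments. For triple against control it passed cell cycle alone. Over libraries left out, the lists past camera ranged from 6 to 10, 7 to 13, 3 to 8 and 8 to 11. Among single genes the sign turned only without a dual library, and none of these was called: TLR7 in dual against control without dual replicate 2 (-0.09, range -0.09 to 0.27), IFNG there without dual replicate 3 (-0.34, range -0.34 to 0.88) and NOS2 in triple against dual without dual replicate 1 (-0.18, range -0.18 to 0.43). Depth limits genes such as IL10, with 3 to 26 counts per library.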

Other observations

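The test of heterophil markers was chosen after its result was seen, and the genes named first were chosen after their values were seen. With both treatments, several genes outside the fixed lists rose over all genes tested. ACOD1, which makes itaconate, rose by log2 2.28 (SE 0.48, edgeR adjusted p = 0.0441), and GCH1, which makes a cofactor of nitric oxide synthase, by log2 1.54 (SE 0.32, edgeR adjusted p = 0.0432). The lysosomal protease gene CTSD stood at 524 ± 59.9 CPM in controls, 1150 ± 260 in the dual and 1280 ± 252 in the triple group (SD, n = 3; log2 1.21 for both treatments, edgeR adjusted p = 0.0385). The galectin gene LGALS3 (log2 1.57, SE 0.26), the fatty acid binding protein gene FABP5 (1.9, SE 0.29) and CDKN1A (1.99, SE 0.28), which encodes the cell-cycle inhibitor p21, also rose. LGR5 fell (log2 -1.37, SE 0.26). These calls were lost without 3 to 8 of the 9 libraries, with an adjusted p of up to 0.22.

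EXFABP is also a heterophil marker, and more heterophils in the treated spleens may be a candidate explanation of its log2 rise of 3.16. The other 12 tested heterophil markers had a median of -1.17, which goes against it. The test was set after this value was seen and cannot settle the question. None of them was called, and their signs differed: LECT2 stood at log2 -1.95 (edgeR adjusted p = 0.47) and AvBD1 at -1.56 (edgeR adjusted p = 0.563), but RSFR at 0.84 (edgeR adjusted p = 0.178) and CSF3R at 0.34 (edgeR adjusted p = 0.518). Within a sex, the median of the whole list for both treatments was -1.48 in females (3 treated, 1 control) and -0.53 in males (3 treated, 2 controls). It was -1.88 and 0.12 for dual against control, and 0.23 and -0.86 for triple against control.

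For both treatments against control, fitted as 2 groups, 1 of the 84 splits of the 9 libraries (the real one) called as many genes as its 186. The highest other split called 26. No smaller share can be had from 84 splits, so chance is made less likely for that count but is not excluded. For the lists past camera, 15 of the 84 splits reached the real 9 and the highest other reached 12, so chance cannot be excluded. For dual against control, 1 of 10 splits called as many genes as the real 59 and the highest other called 0. For its lists, 3 of 10 splits reached the real 8 and the highest other reached 13. For triple against control, 1 of 10 splits called as many genes as the real 36 and the highest other called 0. For its lists, 1 of 10 reached the real 12 and the highest other reached 9. The 10 splits are too few for a share under 0.05.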
